A study of Homo sapiens with 2 samples.

How the data were processed

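RNA sequencing was done on 2 libraries, both labelled as human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein. Per the labels' protocols, cells were held in serum-free medium for 24 h. They were then exposed for 24 h to 5 µM CHIR99021, an inhibitor of the kinase GSK3, together with 100 ng/ml of the growth factor FGF1, or left without both as the control. Total RNA was extracted with Trizol and libraries followed standard Illumina protocols, per the labels' protocols. There is 1 library per group, so no difference below has a replicate check, and no p-value was computed across genes.

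The authors deposited FPKM (fragments per kilobase of transcript, scaled to the size of the library) for each library, per gene and per transcript, per the file headers. The deposited tables also hold the authors' own p-value and q-value for each row. Their column layout is that of a Cuffdiff table, and a legend sheet names cuffcompare. The aligner, the genome build, the annotation and all versions are not given in the sources used here. Of the transcript rows, 99.7% name a reference transcript found in GENCODE release 29 (GRCh38). Of 33202 gene rows with a single symbol that is unique there, 95.5% have a locus containing the GENCODE gene within 50 bases. Coordinates are therefore given from GENCODE release 29. The gene table has 54822 rows, of which 16034 were tested by the authors, and the transcript table has 261287 rows, of which 64621 were tested. The filtered sheets hold rows identical to rows of the full tables and were not used further. Overlapping genes share a row in 1345 gene rows. Such rows hold 12.3% of FPKM in the control library and 12.0% in the treated library. They were left out of gene comparisons, and where a gene is found only in such a row its FPKM is the sum over its transcripts. A row with 1 symbol can also hold transcripts of another gene. In 126 of the 11972 genes compared, the row differed by more than 10% from the sum over the transcripts of its symbol. Genes of chromosome Y, XIST and TSIX were not used.

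Depth was recovered from the low FPKM values. In genes with a single transcript of at least 1500 bases, 1000 divided by the FPKM of a gene with 1 fragment is linear in transcript length. The slope gave scaling totals of 27779550 fragments in the control library and 24285890 in the treated library. Below 20 fragments, 98.0% and 98.1% of such genes came within 0.05 of a whole number of fragments. Estimated fragments per gene gave exact (Clopper-Pearson) 95% intervals of the ratio between libraries, centred on the FPKM ratio. They cover counting error only. The FPKM ratio also depends on the estimated mix of transcripts. It lay outside the interval of the plain fragment ratio in 3918 of 11901 genes, with a median absolute difference of 0.08 on the log2 scale, so intervals of abundant genes are too narrow.

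The main measure was log2((treated FPKM + 1) / (control FPKM + 1)), which understates changes of low genes. It was computed for rows with 1 symbol, the authors' test status OK and a mean FPKM of at least 1, which left 11972 genes. A gene was counted as higher or lower at a 2-fold difference on this scale. Folds given for named genes are plain FPKM ratios. Genes were named by a rule fixed before the data were examined. It took the 15 highest and 15 lowest log2 ratios among genes with a mean FPKM of at least 5 and a transcript of 200 bases or longer. It added up to 4 members of each gene list with the largest ratios, the targets of the treatment and 10 further genes. The last set was AXIN2, LEF1, NKD1, DUSP6, SPRY4, MKI67, CDKN1A, PECAM1, CDH5 and VWF. Heart muscle genes, MMRN2 and the genes of shared rows were named after their values had been seen. In 29 gene lists fixed before the data were examined, members with a mean FPKM of at least 1 were counted as higher or lower at 1.5-fold on the same log2 scale. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. A further 7 lists were chosen after heart muscle genes had been seen. Older symbols were matched through the RefSeq gene table.

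On data simulated for this comparison with 11930 genes, 200 of them changed, the 2-fold rule called 100% of genes raised 4-fold, 92% of genes raised 3-fold, 70% of genes lowered 3-fold and 84% of genes lowered 4-fold. It called 0.239% of unchanged genes. The 95% intervals of the plain fragment ratio held the true ratio in 95.3% to 95.8% of all genes, depending on the fold. They held it in 88% of the 50 changed genes of the fold where that share was lowest. Of 1000 lists of unchanged genes, 5.6% lay outside the central 95% of random medians. The simulation held counting error only, without error in the mix of transcripts or differences between cultures, so none of these shares covers those. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 FPKM, other filters on low values, median centring, TPM scaling (each library rescaled to the same sum), transcript sums, a 1.5-fold rule, all rows, and other thresholds on the authors' values. Added after seeing the data were a correction of log2 ratios for transcript length and GC content (running medians over 50 bins), random lists matched on length too, and the ratio of estimated fragments. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.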

Results

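Expression was measured in 2 libraries labelled HUVEC, 1 left untreated (the control library) and 1 labelled as exposed to 5 µM CHIR99021 and 100 ng/ml FGF1 for 24 h (the treated library). CHIR99021 inhibits GSK3, a kinase that marks beta-catenin for degradation, and FGF1 activates FGF receptors. The series set out to compare genes of angiogenesis, proliferation, senescence and cell death between them. The files imply 27779550 fragments for the control library and 24285890 for the treated library. With 1 library per group, each difference describes these libraries and has no replicate check.

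Transcripts of heart muscle were very abundant in both libraries, and the main endothelial genes were close to 0. MYL7, the atrial myosin light chain, had an FPKM of 16801 in the control library and 7473 in the treated library. Cardiac actin ACTC1 had 4191 and 4188, cardiac troponin T TNNT2 had 4279 and 4685 as the sum of its transcripts, and the cardiac transcription factor NKX2-5 had 423 and 495. PECAM1, an adhesion protein of endothelial junctions, had 0.00542 and 0.104, CDH5 (VE-cadherin) 0.0122 and 0.0799, and VWF 0.0311 in the control library and a listed 0 in the treated library. These values go against the cell type in the labels.

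Over 29 endothelial identity genes, each taken as the sum of its transcripts, the median FPKM was 0.15 in the control library and 0.123 in the treated library, and 24 and 25 of them were below 1. Over 25 sarcomere genes the medians were 512 and 648, and these genes held 8.72% and 7.39% of all FPKM. This list was chosen after the heart genes had been seen. Of the endothelial identity genes, MCAM (67.1 and 38.2) and EGFL7 (11.1 and 5.44) were at 1 FPKM or more in both libraries. So were the VEGF receptor KDR (5.14 and 31.9) and PROCR (1.71 and 3.05), and no others. The gene row of MMRN2 had 1.69 and 1.88, but most of it came from ADIRF-AS1 transcripts (1.53 and 1.66), and the transcripts of MMRN2 itself had 0.161 and 0.217. Of the lymphatic markers, PROX1 had 10.3 and 13.3, PDPN 29.1 and 22.0, and LYVE1 was listed at 0 in the control library and had 0.162 in the treated library. Of the other marker sets, the 13 leukocyte and red cell genes were all below 1 FPKM in both libraries, with no member measured. In the epithelial list KRT8 (737 and 688) and KRT18 (746 and 441) were abundant, while EPCAM had 1.46 and 0.962. The fibroblast and mural markers COL1A1 (84.5 and 100.1), LUM (19.4 and 13.6) and RGS5 (64.4 and 225) were present in both.

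**Figure D1:**
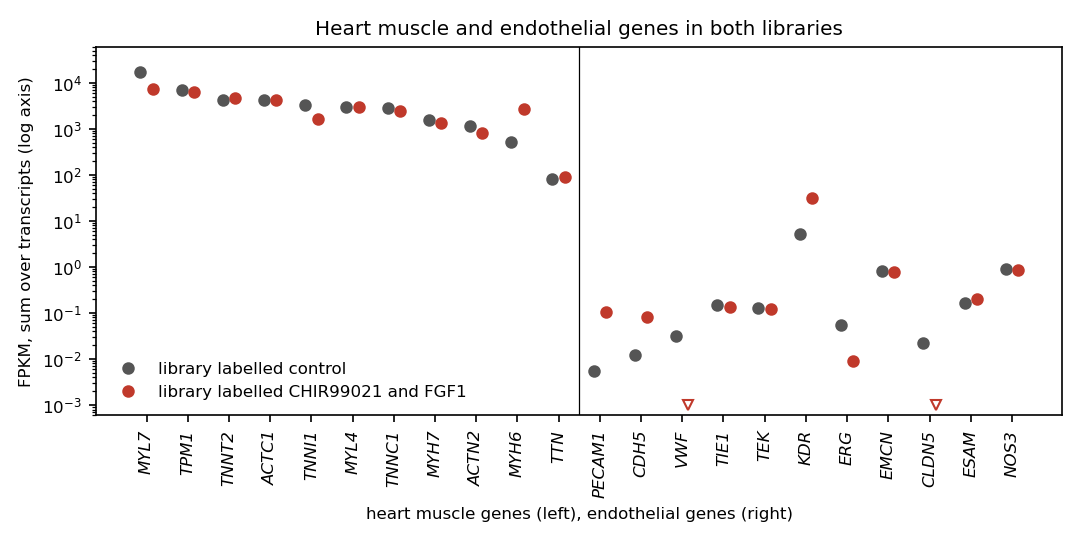
FPKM of 11 heart muscle genes (left) and 11 endothelial genes (right) in the library labelled control (grey) and the library labelled CHIR99021 and FGF1 (red), on a log axis, each point 1 library's sum over the gene's transcripts and open triangles values listed at 0. Heart muscle genes reach 16801 FPKM for MYL7, and of the endothelial genes drawn only KDR is above 1 FPKM.

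Transcripts of early-response transcription factors, of a matrix protein and of an angiogenic ligand were the most elevated in the treated library. FREM2, an extracellular matrix protein, was 46.4-fold higher (95% counting interval 41.8 to 51.5, from 0.831 to 38.5 FPKM). ANGPT1, the ligand of the receptor TEK, was 22.8-fold higher (18.7 to 28.1). The NR4A orphan nuclear receptors were higher together, NR4A1 by 11.9-fold (11.2 to 12.8), NR4A2 by 27.4-fold (19.4 to 40.0) and NR4A3 by 12.2-fold (11.1 to 13.5). By the ratio of estimated fragments NR4A3 was 10.1-fold higher, outside its interval. EGR3, a growth factor-induced transcription factor, was 47.7-fold higher (34.5 to 67.9).

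In all, 545 of 11972 genes were at least 2-fold higher and 305 at least 2-fold lower in the treated library. Others among the 15 highest included ID1 (7.69-fold), a target of BMP signals, KLF10 (8.38-fold), DLK1 (10.1-fold), LEF1 (6.82-fold), a partner of beta-catenin, and RN7SL1 (5.74-fold), the RNA of the signal recognition particle. The pseudogene HMGB1P1 (9.37-fold) and 2 transcripts with clone names were also among them. FREM2 lies on chromosome 13 at 38687129 to 38887131, ANGPT1 on chromosome 8 at 107249482 to 107498055, NR4A1 on chromosome 12 at 52022832 to 52059507 and LEF1 on chromosome 4 at 108047545 to 108168956 (GRCh38, all protein-coding).

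HSPB6, a small heat shock protein, MFAP4, a microfibril protein of the matrix, and C1QL1 had the lowest log2 ratios in the same ranking. HSPB6 had 130 FPKM in the control library and 14.1 in the treated library, 9.23-fold lower (8.37 to 10.2). MFAP4 was 6.46-fold lower (6.12 to 6.82), C1QL1 9.02-fold (6.78 to 12.2) and the lens and muscle chaperone CRYAB 4.30-fold lower (4.14 to 4.46). By the ratio of estimated fragments CRYAB was 4.65-fold lower, outside its interval. The muscle filament gene DES was 4.17-fold lower, the neuronal ubiquitin hydrolase UCHL1 4.03-fold, S100A10 3.73-fold and S100A6 3.51-fold. The rest of the 15 lowest were C10orf54 (5.10-fold), UBALD2 (5.26-fold, or 3.16-fold by the ratio of estimated fragments), RAMP1 (3.89-fold), the antisense transcripts NAV2-AS2 (5.19-fold) and VLDLR-AS1 (4.31-fold), and 2 transcripts with clone names. VLDLR-AS1 was 3.23-fold lower by the ratio of estimated fragments. HSPB6 lies on chromosome 19 at 35754569 to 35758079 and MFAP4 on chromosome 17 at 19383442 to 19387240 (GRCh38, both protein-coding).

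The 15 highest genes had a median transcript length of 2595 bases and the 15 lowest 959 bases. Across genes, which are not independent replicates, longer transcripts had higher ratios, with a Spearman's rho of 0.379. After correction for length and GC content, 446 of 544 higher genes and 196 of 303 lower genes with a known length stayed at least 2-fold apart. All 15 highest and all 15 lowest were among them. These had been chosen for extreme log2 ratios, the smallest in size being -1.77 for S100A6, so their staying says little about the trend. The ratio of estimated fragments is summed over a gene's transcripts and so depends less on their estimated mix. It placed 398 of the 545 higher and 268 of the 305 lower genes at least 2-fold apart the same way.

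**Figure D2:**
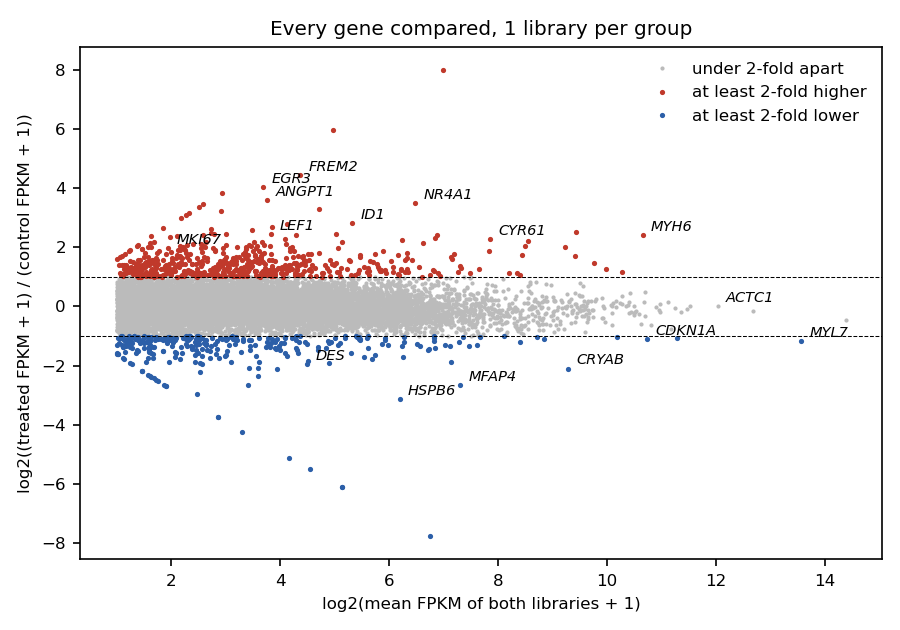
Log2 ratio of the treated over the control library against log2 of the mean FPKM plus 1 for each of 11972 genes, 1 point per gene, with dashed lines at 2-fold; red points (545) were at least 2-fold higher and blue points (305) at least 2-fold lower. Unnamed points beyond FREM2 and HSPB6 were left out of the ranking because their transcripts are shorter than 200 bases or their mean FPKM is below 5.

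**Figure D3:**
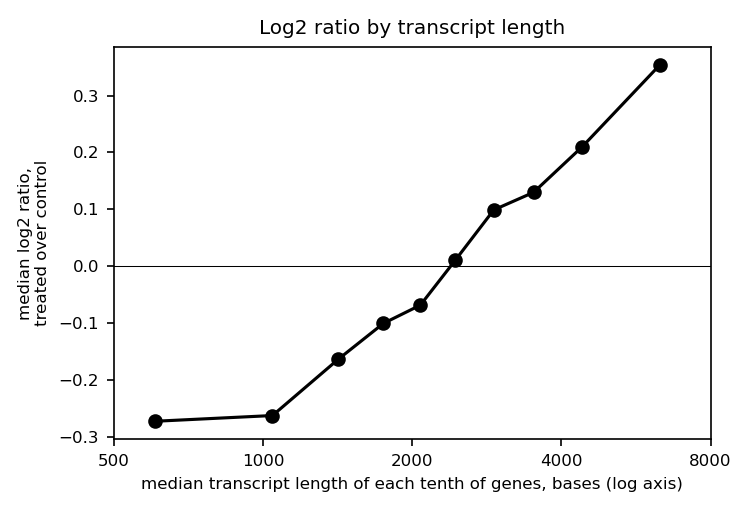
Median log2 ratio of the treated over the control library in 10 groups of 11959 genes ordered by transcript length, against the median length in bases on a log axis. The median goes from -0.27 in the group of shortest transcripts to 0.35 in the longest.

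Genes of cell division were higher in the treated library, nearly all of the G2/M list and most of the S-phase list. Of 27 measured G2/M genes, 25 were at least 1.5-fold higher and none was 1.5-fold lower. MKI67, a marker of cycling cells, was 9.32-fold higher (7.75 to 11.3, from 0.552 to 5.15 FPKM), the kinetochore gene CENPF 7.15-fold (5.86 to 8.81), the spindle genes TPX2 5.71-fold (4.89 to 6.71) and NUSAP1 5.14-fold (4.19 to 6.35). Of 25 S-phase genes, 15 were higher and none lower, with the replication licensing factor CDT1 4.91-fold, RRM2 3.04-fold, TK1 2.73-fold and E2F8 2.30-fold higher. The median log2 ratio was 1.60 for G2/M and 0.66 for S phase, each above all of 10000 random lists (percentile 100). Of 9 measured histone genes, 8 were lower and none higher, with a median of -0.89 (percentile 0), HIST2H2BE 2.79-fold and HIST1H1C 2.55-fold lower.

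Feedback genes of the FGF and ERK pathway and part of the WNT targets were higher in the treated library. Of 24 FGF and ERK genes, 17 were higher and 1 lower, with a median of 0.93 (percentile 100). Besides EGR3 these included EGR1 (3.76-fold), EGR2 (8.08-fold, or 4.58-fold by the ratio of estimated fragments), the ERK phosphatase DUSP6 (3.12-fold, 2.83 to 3.45) and the inhibitor SPRY4 (3.01-fold, 2.77 to 3.27). By the ratio of estimated fragments DUSP6 was 2.44-fold higher, outside its interval. Of 19 WNT targets, 8 were higher, 1 lower and 10 between, with a median of 0.44 (percentile 99.9). LEF1 was 6.82-fold higher (5.66 to 8.28), TNFRSF19 3.32-fold, MYC 3.26-fold and BAMBI 2.49-fold. AXIN2, the feedback inhibitor of the pathway, was found only in a row shared by several genes. The sum of its transcripts was 7.30-fold higher (6.22 to 8.61), or 5.87-fold by the ratio of estimated fragments, outside that interval. NKD1 was below 1 FPKM in both libraries, at 0.119 and 0.691.

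Of the targets of the treatment, GSK3B was 1.71-fold higher, while CTNNB1 (beta-catenin) had 185 FPKM in the control library and 175 in the treated library. FGFR1, the main FGF receptor here, had 43.1 and 54.3, and FGFR2 was 3.64-fold higher (2.95 to 4.52). FGFR4 (1.55 and 0.657, 1.37-fold lower by the ratio of estimated fragments), SDC1 (7.18 and 4.38) and SDC4 (59.5 and 35.5) were lower. FGF1 had 13.9 and 11.7 FPKM, FGFRL1 10.3 and 8.68, GSK3A 44.5 and 35.8 as the sum of its transcripts, FGFR3 0.121 and 0.254, and KLB was listed at 0 in both libraries. Of 9 measured targets, 2 were higher and 3 lower, with a median of -0.22 (percentile 14.3), or 1 and 2 after length and GC correction.

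BMP and TGF-beta response genes were higher together. Of 19, 15 were higher and none lower, with a median of 1.06 (percentile 100). ID1 was 7.69-fold higher (6.66 to 8.92), the ligand BMP2 5.61-fold (5.07 to 6.21), ID4 5.63-fold (4.82 to 6.62) and the inhibitory SMAD7 3.47-fold. Of 26 mesenchymal genes, 10 were higher and 1 lower, with a median of 0.31 (percentile 99.9). The matricellular genes CYR61 (4.85-fold) and CTGF (4.04-fold) and the smooth muscle genes ACTA2 (3.23-fold) and TAGLN (1.75-fold) had the largest log2 ratios with the pseudocount of 1 FPKM. Of 17 mural cell and fibroblast markers, which share ACTA2 with that list, 7 were higher and 1 lower, with a median of 0.53 (percentile 100). RGS5 was 3.49-fold (5.15-fold by the ratio of estimated fragments) and MYH11 5.22-fold higher, and DES was lower.

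Genes that promote angiogenesis tended to be higher in the treated library. Of 20 measured angiogenic genes, 8 were higher and 3 lower, with a median of 0.43 (percentile 99.9). ANGPT1 led the list, KDR was 6.21-fold higher (5.76 to 6.70) and VEGFC 3.78-fold (3.18 to 4.51), while the chemokine CXCL12 was 2.45-fold lower (2.25 to 2.67). Of 10 inhibitors of angiogenesis, 3 were higher and 1 lower, with a median of 0.32. THBS1 was 3.71-fold higher (3.65 to 3.77), ADAMTS1 3.71-fold and SEMA3A 2.14-fold higher, and TIMP1 2.04-fold lower. By the ratio of estimated fragments THBS1 was 3.05-fold higher, outside its interval, ADAMTS1 3.04-fold and SEMA3A 1.51-fold. The percentile of this list was 97.8 among lists matched on expression and 86.1 when length was matched too. Of 11 arterial and Notch genes, 5 were higher and 1 lower, with a median of 0.58 (percentile 99.8), GJA5 10.2-fold, UNC5B 2.51-fold, HES1 2.23-fold and HEY2 2.12-fold higher. Of 5 venous genes, 1 was higher and LEFTY2 was 4.49-fold lower, with a median of 0.40 (percentile 87.3). In the control library 24 of 29 endothelial identity genes were below 1 FPKM, and in the treated library 25. The lists of this paragraph therefore cannot be read as changes in endothelial cells.

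Individual genes of senescence and cell death were lower in the treated library, while their lists lay within the central 95% of random lists matched on expression. CDKN1A (p21), an inhibitor of cell cycle kinases, had 2310 FPKM in the control library and 1082 in the treated library, 2.14-fold lower (2.11 to 2.16). That interval covers counting error only, and the ratio of estimated fragments gave 2.18-fold, outside it. GDF15 was 2.81-fold and the collagenase MMP1 2.52-fold lower, and the nuclear lamin LMNB1 2.87-fold higher (2.47 to 3.35). By the ratio of estimated fragments LMNB1 was 2.15-fold higher, outside its interval. Of 21 senescence genes, 3 were higher and 5 lower, with a median of -0.19 (percentile 8.89). Of 24 p53 targets none was higher and 4 were lower, with a median of -0.14, BBC3 2.98-fold, TP53I3 1.73-fold and SESN1 1.66-fold lower. The percentile of this list was 18.6 among lists matched on expression, 6.89 when length was matched too and 0.26 after length and GC correction, where the median was -0.25. Of 26 death effectors none was higher and 5 were lower, with a median of -0.18 (percentile 3.97). They included BBC3. Of 15 survival genes 2 were higher, BIRC5 by 7.30-fold (5.50 to 9.83) and IER3 by 2.54-fold, and none lower, with a median of -0.02 (percentile 59.5) that was 0.08 under TPM scaling.

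Of 24 stress response genes none was higher and 5 were lower (median -0.12, percentile 26.2), TRIB3 by 2.13-fold and DDIT3 by 1.56-fold among them. After length and GC correction 2 were lower. By the ratio of estimated fragments TRIB3 was 1.49-fold lower. Of 12 heat shock genes none was higher and 3 were lower (median -0.32), CRYAB and HSPB1 (1.70-fold) among them. The percentile of this list was 5.90, but 1.81 when length was matched too and 0.72 after length and GC correction. Of 21 cholesterol genes 1 was higher and 4 were lower (median -0.23, percentile 4.61), or 1 and 1 after length and GC correction. Of 26 hypoxia and glycolysis genes 6 were higher and 5 lower (median -0.09, or 0.01 under TPM scaling, percentile 37.6), SLC2A3 2.39-fold higher and EGLN3 2.35-fold lower. Of 11 interferon genes 3 were higher and 4 lower (median -0.25, or 0.06 under TPM scaling, percentile 6.34, or 0.61 after length and GC correction), and of 9 inflammatory adhesion genes only VCAM1 was higher, by 2.46-fold (median 0.13, percentile 68.6).

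Of 33 ribosomal protein genes 1 was lower, RPLP1 by 1.52-fold, and none higher (median 0.03, percentile 97.2). With length matched too the percentile was 100, and after length and GC correction 5 were higher and none lower (percentile 99.9). Of 5 measured endothelial identity genes KDR was higher, EGFL7 (2.03-fold) and MCAM (1.76-fold) were lower, and the median, set by the MMRN2 row, was 0.10 (percentile 61.1), or -0.11 with transcript sums. Of 4 lymphatic genes RELN (3.37-fold, or 1.70-fold by the ratio of estimated fragments) and CCL21 (2.73-fold) were lower and none was higher. The median was -0.85 (percentile 0.05), or -0.55 by the ratio of estimated fragments. Of 5 epithelial genes KRT19 was 1.65-fold higher and KRT18 1.69-fold lower (median -0.33, percentile 15.9). Only 2 mitochondrially encoded genes had a row of their own, too few for a percentile, and neither was 1.5-fold apart. MT-CYB had 24826 and 17867 FPKM.

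**Figure D4:**
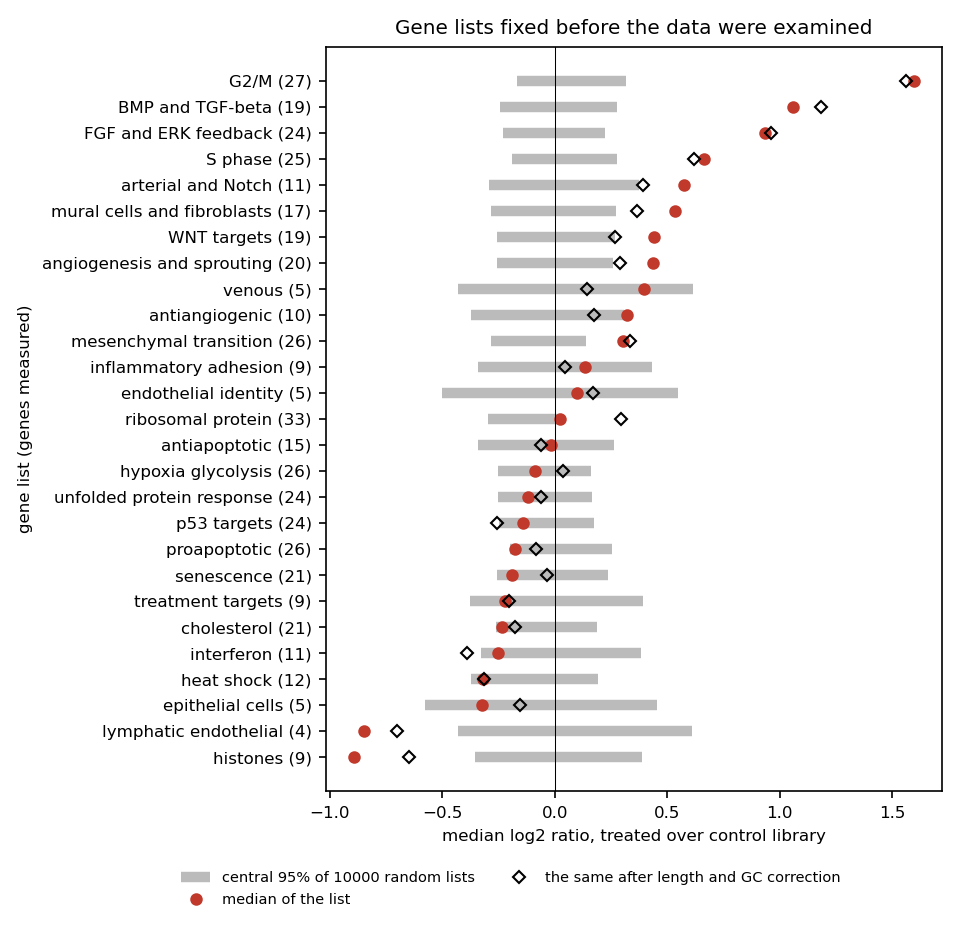
Median log2 ratio of the treated over the control library for each list with at least 3 measured genes (red points), the same after length and GC correction (open diamonds) and the central 95% of 10000 random lists matched on mean expression (grey bars), with the number of measured genes in brackets. G2/M genes lie farthest to the right at 1.60 and histone genes farthest to the left at -0.89.

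At the level of transcripts, 5344 of 34862 were at least 2-fold higher and 4079 at least 2-fold lower in the treated library. For all 30 of the highest and lowest genes, NR4A1 and HSPB6 among them, the most abundant transcript differed in the same direction as the gene. In the authors' deposited table of transcripts, 0 of 64621 had a q-value of 0.05 or less, and 1608 had an unadjusted p-value of 0.05 or less.

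In the authors' deposited table of genes, 43 of 16034 tested rows had a q-value of 0.05 or less, and 780 had an unadjusted p-value of 0.05 or less. Of the 43, 37 were higher and 6 lower in the treated library, but 7 were listed at 0 in 1 library and 9 had a mean FPKM below 1. FHAD1 and RPE65 were at 0 in the control library, and ITIH3 and CPA1 in the treated library. In the authors' deposited table FREM2, ANGPT1, NR4A1, NR4A2, NR4A3, ID1, KLF10, BMP2, KDR and MFAP4 had a q-value of 0.0243 and LEF1 0.0373, while EGR3 had 0.591, MKI67 0.145, HSPB6 0.654, C1QL1 0.202 and CRYAB 0.0802. By the authors' deposited table, 9 of the 15 highest and 1 of the 15 lowest genes had a q-value of 0.05 or less. The series' design text gives 815 changed genes of 18845 at an adjusted threshold, which is neither count. The authors' values compare the reads of these libraries, not the conditions.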

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

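Rows of the gene table that name several overlapping genes were outside the gene comparison, and 18 of 841 such rows with a mean FPKM of at least 1 were at least 2-fold higher in the treated library than in the control. The highest was the row of PVT1, a noncoding neighbour of MYC, with 5.90 FPKM in the control library and 31.9 in the treated library. The row holding AXIN2 had 4.86 and 19.8, and the row holding KIAA0101, a PCNA-binding replication factor, had 4.06 and 12.0. A further 14 were at least 2-fold lower. In such a row the reads of overlapping genes are added up, so the values belong to the locus and not to a named gene.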

How the results depend on the processing

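Median centring, transcript sums, no filter on low values and all rows kept both gene counts within 1.5 times of 545 and 305. So did length and GC correction and the ratio of estimated fragments, both added after seeing the data. Similar counts hide changed members, since by the ratio of estimated fragments only 398 of the 545 higher and 268 of the 305 lower genes stayed. A pseudocount of 0.1 FPKM gave 852 higher and 556 lower genes, 5 FPKM gave 213 and 92, a mean of at least 5 FPKM 329 and 150, and a 1.5-fold rule 1566 and 1240. These follow from shrinking low genes less or more, from fewer genes considered and from a laxer rule. TPM scaling gave 957 higher genes among 13364 with a median log2 ratio of 0.10. This follows from rescaling libraries whose FPKM sum to 575963 and 537249, and from larger values, on which the pseudocount and the filter weigh less. The authors' deposited table held 0 genes at a q-value of 0.01 or less, where its smallest q-value is 0.0243, and 780 at an unadjusted p-value of 0.05 or less. At a mean of at least 5 FPKM, 1401 transcripts were higher and 1320 lower, from fewer transcripts considered. Of the recomputed list medians 185 stayed within the spread of random lists of their size and 3 moved beyond it, though medians near 0 of the survival, interferon, hypoxia, inflammatory, stress response and endothelial lists changed sign under some settings. The G2/M median was 2.06 with a pseudocount of 0.1 FPKM, the endothelial identity median was -0.80 at a mean of at least 5 FPKM, where few of its genes remain, and the ribosomal protein median was 0.29 after length and GC correction, whose cause was not tested. After length and GC correction, 7 WNT targets were higher and 2 lower, 4 arterial and Notch genes higher and 0 lower, 8 mesenchymal genes higher and 0 lower, 2 endothelial genes higher and 2 lower, 1 heat shock gene higher and 2 lower, and 1 epithelial gene higher and 0 lower. Of the recomputed log2 ratios of the 30 highest and lowest genes, 122 stayed within counting error or 0.1, 28 moved beyond both and none changed sign. No paired analysis was possible because each group has 1 library, which also rules out leaving a library out. Depth limits endothelial genes near 0, where a few fragments decide a ratio.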

Other observations

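The gene lists of this paragraph and the next were chosen after the values they concern had been seen. So were the tests on the cell type and on fibroblasts and mural cells, and the length and GC correction. Sarcomere genes of the libraries labelled HUVEC lay as a group within the range of random lists, with some members far apart. Of 22 measured sarcomere genes 4 were at least 1.5-fold higher and 6 lower in the treated library (median -0.17, percentile 35.9). MYH6, the fast atrial myosin heavy chain, was 5.30-fold higher and MYL3 2.75-fold higher, while MYH7 had 1556 FPKM in the control library and 1363 in the treated library. MYL7 was 2.25-fold, TNNI1, the fetal troponin I, 2.10-fold and LMOD2 3.31-fold lower. TNNI3, the adult troponin I, was 3.89-fold lower as the sum of its transcripts in a shared row. Of 17 calcium and ion channel genes 8 were higher and 2 lower (median 0.39, percentile 99.8, or 93.3 with length matched too), or 4 and 3 after length and GC correction. Without that correction the exchanger SLC8A1 was 3.54-fold and the pacemaker channel HCN4 2.74-fold higher, and phospholamban PLN 2.04-fold lower. Of 12 cardiac transcription factors 4 were higher and 1 lower (median 0.27, percentile 98.1, or 96.7 with length matched too), TBX20 by 4.86-fold, TBX2 by 2.22-fold and HAND2 2.11-fold lower.

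Of 17 genes of the CREB early response 10 were higher and 1 lower (median 1.02, percentile 100), led by the NR4A genes from which the list was prompted. Of 26 nuclear genes of the respiratory chain 8 were lower and none higher (median -0.37, percentile 0.49, or 7.42 with length matched too). NDUFA4 was 1.89-fold and COX5B 1.83-fold lower. After length and GC correction 2 genes of this list were lower, with a median of -0.14. Of 16 fatty acid genes 1 was lower (median -0.17, percentile 15), and of 18 YAP and TAZ targets 6 were higher and 1 lower (median 0.21, percentile 95.5, or 68.9 with length matched too), led by CYR61 and CTGF. After length and GC correction the median of the YAP and TAZ targets was -0.02 (percentile 39.6).

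The heart muscle transcripts are the widest departure from the labels. The median endothelial identity gene was at most 0.15 FPKM in either library, and PECAM1, CDH5 and VWF reached at most 0.104, which argues against endothelial cells mixed with heart muscle. Gene names shifted against the values are argued against by ribosomal protein genes, whose median lay at percentile 99.9 or above. The endothelial values also argue against the labelled cells as the main source. Heart muscle cells in their place remain, with sarcomere medians of 512 FPKM in the control library and 648 in the treated library. The endothelial list was fixed beforehand, the heart list was not, and where such a replacement arose cannot be seen from the files.

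Genes higher in the treated library had longer transcripts. After correction for length and GC content, 75.8% of the genes at least 2-fold apart stayed so. Medians of genes grouped by length ran only from -0.27 to 0.35, which argues against the length trend as their whole cause. The share itself adds little, since a trend of that size could mostly remove genes near the 2-fold line. With the GC trend removed, rho between length and ratio was still 0.350, against a difference in GC content. Within 7616 genes with several transcripts, the longest was shifted up relative to the shortest in 49.5% (Wilson 95% interval 48.4% to 50.7%), so no upward shift of longer transcripts was seen. The interval includes 50%, the share without such a bias, so these values show none between the longest and shortest transcripts. A bias on transcripts is still kept open, because estimates within a gene depend on each other. RNA quality may also differ between the libraries and was not tested.

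G2/M genes were higher in the treated library, with a median log2 ratio of 1.60, or 1.56 after length and GC correction. Medians of genes grouped by length ran only from -0.27 to 0.35. A length trend of that size is too small to be the whole cause, so the correction itself could hardly have removed the difference. Summed over the list, estimated fragments were 2754 in the control library and 10671 in the treated library, a ratio of 4.43 once scaled to the library totals, with a lower bound of 4.25, which argues against counting error. The 8 fibroblast markers of the fixed list had a median log2 ratio of 0.46 (SD 0.50), COL1A1 0.24 and COL6A3 1.16 among them. This leaves a larger share of fibroblasts open, since higher levels in the control library would hide a small share. Only 3 markers were no higher there than the highest G2/M gene (9.13 FPKM), and the median G2/M gene had 1.12 FPKM. A larger share of mural cells also stays open, since the 9 mural markers had a median of 0.53 with an SD of 1.17. They ran from the muscle filament gene DES at -1.94 to RGS5 at 1.79. The 5 mural markers no higher in the control library than the highest G2/M gene had a median of 0.14. As a hypothesis, more cells may have been cycling under CHIR99021 and FGF1, which 1 library per group cannot separate from a difference between cultures and which counts of dividing cells in replicate cultures would test.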
